A study of Sus scrofa with 6 samples.

How the data were processed

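Alveolar macrophages were collected from 6 pigs by bronchoalveolar lavage, and total RNA was extracted with Trizol, per the labels' protocols. From 6 µg of RNA per pig, biotin-labelled cRNA was prepared and hybridised to 1-colour Affymetrix porcine arrays, per the labels' protocols. The deposited values are intensities, 1 linear signal per probe set and array, for 24123 probe sets and 6 arrays. The submitters' processing notes name MAS5 as the tool. Its version, scaling target and any detection calls are not given in the sources used here. The trimmed mean signal per array, leaving out 2% at each end, was 234, 254 and 234 in infected replicates 1, 2 and 3 and 237, 234 and 384 in control replicates 1, 2 and 3, so the arrays were not all at 1 common scale. The lowest signal was 1 and the highest 20778.3. How many probe sets were above background in each array could not be set from the values used here.

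Samples were grouped by their labels as 3 infected and 3 control pigs, each labelled as a biological replicate. Gene names came from the platform annotation of the array, in which 10099 probe sets had 1 gene symbol, 198 had several and 13826 had none. Of these, 9989 matched a gene of the RefSeq table of assembly Sscrofa11.1 by identifier, which changed 0 symbols. No gene was named from a probe set with several symbols, and no coordinates were used because the series gives none.

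Signals were converted to log2 and otherwise kept as deposited. The 124 control probe sets were left out, which left 23999, and probe sets with a mean log2 signal under the 40th percentile (a signal of 47.9) were left out as dim. The remaining 14399 probe sets were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend on mean signal), infected against control, two-sided, with Benjamini-Hochberg adjustment over all probe sets tested and a threshold of 0.05. Of these, 7381 had 1 symbol, for 5453 genes. Fold changes below are on the scale of the MAS5 signal, and whether a dim probe set was above background is not known without detection calls.

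For gene lists, each gene was represented by the probe set with the highest mean log2 signal. The 32 lists covered immune pathways, macrophage functions, housekeeping and stress genes and markers of other cells that a lung lavage can hold. The 29 lists with at least 5 tested genes were compared with all other named genes by limma's camera with a preset correlation of 0.01, adjusted by Benjamini-Hochberg over the lists. Camera with an estimated correlation and fry were run as alternatives. The list mean per array, as a deviation from the average of all arrays and relative to all tested genes, was compared by an exact permutation test, two-sided.

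Genes were named by a fixed rule. Per direction it took 12 genes past the adjusted threshold with no overlap between the groups, by size of the fold change, and filled missing places by the smallest unadjusted p among probe sets with 1 symbol. All 24 places were filled in that second way. It also took up to 4 members with the smallest unadjusted p of every list past its test and of every list of other cells, and further list members past the adjusted threshold, of which there were 0. The design, the lists, the naming rule and the main alternatives were fixed before the data were examined.

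The alternatives were no filter, a filter at the 60th percentile, an offset of the 20th percentile signal (22.4) before log2, quantile normalization, centring of each array on its median, the replicate number as a block, array weights, eBayes without a trend, leaving out each pig in turn, the 3' to 5' ratio as a covariate, and the mean of all probe sets of a gene. Quantile normalization without control replicate 3 and the exact test of list means per array were added after seeing the data. The fit and the list test were tested on 20 simulated data sets of 14399 probe sets, infected against control, with the spread of the real arrays. The limma fit recovered 13.1% of probe sets changed 2-fold and 89.7% of those changed 4-fold, with 7.75 false calls per data set. A T cell list shifted by 0.5 on the log2 scale passed camera in 20 of 20 data sets, with 0.15 other lists passing per data set. The probe sets were drawn independently of each other, so the genes of a list were not correlated. In the real arrays the lists that passed camera had estimated correlations of 0.23 to 0.75. All simulated arrays of a probe set also had the same spread, without an array that stood apart as control replicate 3 did. The simulation therefore gives neither the rate of false lists nor the share of changed probe sets recovered in the real arrays.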

Results

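The transcriptome of porcine alveolar macrophages, the resident phagocytes of the airspaces, was compared between 3 pigs infected with Haemophilus parasuis serotype 4 and 3 control pigs. Haemophilus parasuis is a Gram-negative bacterium of the pig airway and the agent of Glässer's disease. The pigs were 28 days old when they received 2 ml of bacteria or of PBS, and the lungs were lavaged 28 days later. The labels differ on whether the inoculum went into the nose or into the trachea. RNA of each pig was hybridised to 1 Affymetrix porcine array, so each array is a separate animal. The median signal of the arrays was 64.8, 68.6 and 65.1 in infected replicates 1, 2 and 3 and 65.4, 66.0 and 103 in control replicates 1, 2 and 3. The number of arrays limits the precision of every comparison, and the median half-width of the 95% confidence interval of a log2 fold change was 0.70.

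Control replicate 3 stood apart from the other 5 arrays. Its Pearson correlations of log2 signal with them were 0.936 to 0.949, against 0.974 to 0.986 among those 5. It also separated from them on the first principal component, which held 66.6% of the variance, whereas control replicate 2 separated on the second, which held 14.0%. The components were taken from the signals as deposited, so the separation of control replicate 3 includes its higher overall signal. Its median log2 signal was 6.68, against 6.02 to 6.10 in the other arrays. The 3' to 5' signal ratio of the ACTB and GAPDH control probe sets, a measure of RNA integrity, averaged 2.54 ± 0.41 on the log2 scale in infected pigs and 2.31 ± 0.68 in controls (SD, n = 3 each; exact permutation p = 0.6, two-sided). With 3 animals against 3, the smallest exact p that can be reached is 0.1. The 3' signals were above the 5' signals in every array. The mean log2 ratio ran from 1.60 in control replicate 3 to 3.001 in infected replicate 2. For ACTB alone it averaged 3.16 in infected pigs and 2.59 in controls, and for GAPDH alone 1.93 and 2.04. The test compares the groups only and does not show that the RNA was intact in either group. The median log2 fold change of all 14399 tested probe sets, infected against control, was -0.20, and quantile normalization of the arrays moved it to 0.011. Values of single genes below are therefore given relative to that median of -0.20 unless they are called fitted values, and the text says where scaling turned a direction.

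The first comparison asked which genes differed between macrophages of infected and control pigs. In infected pigs the signals of CXCR6, a chemokine receptor of tissue-resident T cells, of LTB, the lymphotoxin beta of lymphocytes, and of LCK, the proximal kinase of the T cell receptor, were above those of controls in all 3 animals. The fitted folds were 3.47 for CXCR6, 2.59 for LTB and 2.35 for LCK. The same held for C1H15orf48, which encodes a small mitochondrial protein induced in inflammation (fitted fold 3.30), and for S100A4, a calcium-binding protein of migrating cells (fitted fold 2.62). In the opposite direction, the fitted log2 fold change was -1.18 ± 0.28 for FAM13A and -1.11 ± 0.30 for TBC1D1, a regulator of glucose transporter traffic (SE, n = 3 per group). None of these genes passed the test across all genes.

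By limma with Benjamini-Hochberg adjustment, 0 of 14399 probe sets had an adjusted p under 0.05, and 0 had one under 0.1. The smallest adjusted p was 0.911. At an unadjusted p under 0.05 there were 299 probe sets, 86 higher and 213 lower in infected pigs, against 719.95 that chance alone gives on average. The 3 infected values did not overlap the 3 control values in 7.42% of probe sets, where chance gives 10%. A 2-fold difference together with an unadjusted p under 0.05 was reached by 135 probe sets, 49 higher and 86 lower. This split depended on the scaling, with 74 higher and 30 lower after quantile normalization and 74 higher and 26 lower after centring each array on its median. The count of genes past the adjusted threshold by limma was also 0 with no filter, with quantile normalization and without control replicate 3, where the smallest adjusted p was 0.124. It became 4 with array weights, 1 without infected replicate 3 and 5 without control replicate 1. With the replicate number as a block it became 82 (38 higher, 44 lower), in a fit with 2 residual degrees of freedom. The count at 2-fold and an unadjusted p under 0.05 was 889 without control replicate 1 and 232 without infected replicate 2.

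Because no gene passed, the 12 probe sets per direction with the smallest unadjusted p were taken as a description. Each of the 24 genes kept its direction in every alternative in which the direction was checked. These were all 15 for 16 of the genes and 14 for the others, since the stricter filter left those out. The fit with the 3' to 5' ratio as a covariate was not among them. That the directions held was largely set by how the genes were picked. Where the groups do not overlap, leaving out a pig cannot turn the direction, and the block leaves the fitted value as it was. Leaving out 1 pig moved 3 of the 24 relative values below by over 1.5 times, that of HSP70.2 to 0.89 without control replicate 3, that of HK3 to -0.61 without control replicate 1 and that of MGLL to -0.77 without infected replicate 2. On the higher side, C1H15orf48 had a log2 signal of 6.95 ± 0.19 in infected and 5.23 ± 0.69 in control pigs (SD, n = 3 each), which is 1.92 above the median of all probe sets. S100A4 had 8.27 ± 0.19 against 6.88 ± 0.38, 1.58 above that median. CXCR6 stood at 7.71 ± 0.19 against 5.91 ± 0.85, a relative value of 1.99. The relative log2 values of the lymphocyte genes LTB and LCK were 1.57 and 1.43. EGR1, an immediate early transcription factor, stood at 1.69, and HSP70.2, a stress-inducible chaperone, at 1.34, with all 3 of its probe sets higher in infected pigs. The relative value was 1.60 for TIMP1, an inhibitor of matrix metalloproteinases, 1.30 for VCAM1, an adhesion molecule for leukocytes, and 1.59 for RNF128, a ubiquitin ligase known for its part in T cell anergy. GBP1, an interferon-induced GTPase that acts against intracellular microbes, had the largest value of these 12 at 2.13, with overlapping groups. LOC102160313, an uncharacterised gene, had 1.71, but its other tested probe set had a fitted log2 fold change of -0.74.

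On the lower side, LRRFIP1, a cytosolic sensor of nucleic acids, had a relative log2 value of -1.97, and its log2 signal was 5.84 ± 0.42 in infected and 8.01 ± 1.47 in control pigs (SD, n = 3 each). All 4 of its probe sets were lower, with fitted log2 fold changes from -2.17 to -0.15. FN1, the matrix protein fibronectin, had -1.81 by its dimmer probe set and -0.77 by its brighter one. In both LRRFIP1 and FN1 control replicate 1 was the lowest control, at 6.32 and 5.50, while control replicates 2 and 3 were between 7.24 and 8.92. NPG4, the antimicrobial peptide protegrin 4, had -2.18 with overlapping groups. HK3, a hexokinase of myeloid cells, had -1.21, although 2 of its 3 probe sets were higher in infected pigs. The relative values of MGLL, a lipase of monoglycerides, and of SRSF5, a splicing factor, were -1.17 and -0.96, and those of FAM13A and TBC1D1 were -0.99 and -0.91. The remaining 4 genes were ROPN1L at -0.70, PNP, a purine salvage enzyme, at -0.64, CYP7A1, named for the rate-limiting enzyme of bile acid synthesis, at -0.63, and FHL1 at -0.61.

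**Figure D1:**
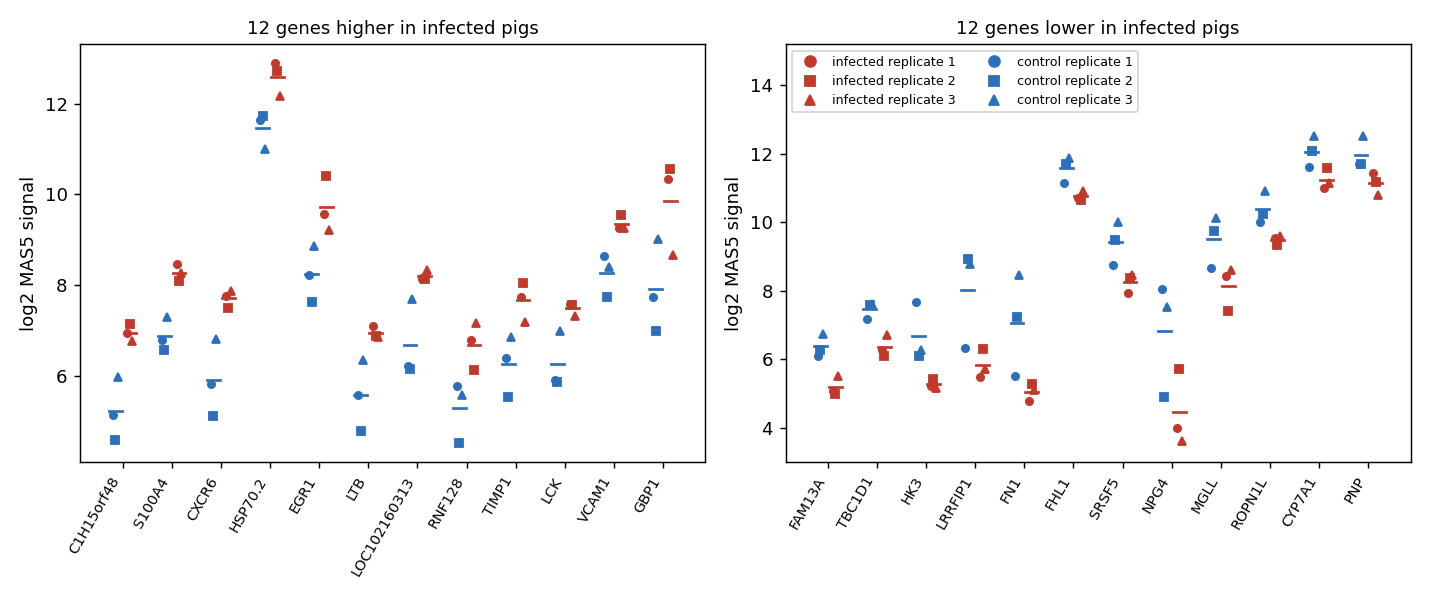
Log2 MAS5 signal (y axis) of the 12 genes per direction with the smallest unadjusted p, with 1 point per pig (red, infected; blue, control; the marker shape gives the replicate number) and a bar at each group mean. No gene passed the adjusted threshold, and for GBP1 and NPG4 the groups overlap.

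The second comparison asked whether groups of functionally related genes shifted together. Markers of T cells, of natural killer cells and of monocytes, inflammatory cytokines and chemokines, and genes induced by interferon gamma or by type I interferon were higher in infected pigs relative to the other genes, as were genes of MHC class I presentation. Cell cycle genes were lower. These 8 of 29 tested lists, 7 higher and 1 lower, passed limma's camera test with its preset correlation of 0.01 and Benjamini-Hochberg adjustment. None of the 8 passed when camera estimated the correlation within each list (adjusted p from 0.836 to 0.965), and 0 passed by fry, limma's test of a list on its own, where the smallest adjusted p was 0.933. List medians are given relative to the median log2 fold change of the tested named genes, which was -0.18, and are log2 values. The number of members past the adjusted threshold over all genes tested was 0 in every list, and leaving out 1 pig moved the relative value of 39 of 82 named probe sets by over 1.5 times.

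Genes of T cells formed the list with the smallest camera p. Of 15 tested members 12 lay above the median of the tested genes, and the list median was 0.53 (camera adjusted p = 5.1e-09). The adjusted p was 0.836 with an estimated correlation. The members with the smallest p were LCK at 1.43, CD3G, a chain of the T cell receptor complex, at 1.34, CD8A, the coreceptor of cytotoxic T cells, at 1.30, and CD2, an adhesion receptor of T cells, at 0.79. The 3 members below the median were LAT, an adaptor of the T cell receptor, at -0.54, CD8B, the other chain of the CD8 coreceptor, at -0.35 and CCR7, a chemokine receptor, at -0.057, and the fitted values of LAT and CD8B were above 0 without control replicate 3 (0.045 and 0.26). An unadjusted p under 0.05 was reached by 3 members, all higher, and 0 passed when adjusted over the list alone. The mean of the list was above 0 in each infected pig and below 0 in each control, 0.25 ± 0.10 against -0.25 ± 0.12 (SD of the array means, n = 3 each; exact permutation p = 0.1, the smallest possible). The call held in all 15 alternatives that kept the preset correlation, with adjusted p from 5.7e-11 to 0.00121, and the median was 0.20 with the stricter filter, 0.25 with no filter or with array weights and 0.28 without control replicate 3.

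Natural killer and cytotoxic cell markers had a median of 0.52 with 6 of 7 members above the median of the tested genes (camera adjusted p = 0.00046; adjusted p = 0.951 with an estimated correlation). CTSW, a protease of cytotoxic lymphocytes, had a relative value of 0.84, KLRK1, the activating receptor NKG2D, 0.97, and CCL5, a chemokine of activated lymphocytes, 0.61, whereas PRF1, the pore-forming protein perforin, had -0.085. No member passed when adjusted over the list alone (count 0). Infected replicates 1 and 2 had list means of 0.46 each, and infected replicate 3 had -0.25, inside the control range of -0.34 to -0.14. The list median was 0.26 without infected replicate 1, 0.84 without infected replicate 3 and 0.31 without control replicate 3. Monocyte markers had a median of 0.38 with 10 of 13 members above the median of the tested genes (camera adjusted p = 2.1e-05; adjusted p = 0.951 with an estimated correlation). Adjusted over the list alone, 2 members passed by limma, S100A4 and TIMP1, against 0 over all genes tested. S100A12, a calgranulin, had 0.68 and VCAN, the proteoglycan versican, had -0.89. These became 0.17 and -0.31 without control replicate 3, and S100A12 had 1.25 without control replicate 1 while VCAN had -1.70 without control replicate 2 and -0.45 without infected replicate 3. The array means of the monocyte list overlapped between groups, 0.19 ± 0.38 against -0.19 ± 0.33 (SD, n = 3 each; exact permutation p = 0.2), and the list median was 0.072 without infected replicate 1 and 0.17 without control replicate 3.

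Inflammatory cytokines and chemokines had a median of 0.37, with 12 of 16 members above the median of the tested genes (camera adjusted p = 4.6e-05; adjusted p = 0.951 with an estimated correlation). CCL8 and CCL2, chemokines that attract monocytes, had relative values of 1.90 and 1.10, and IL18, an inflammasome-processed cytokine, had 1.08. CXCL2, a chemokine for neutrophils, had -0.75. Adjusted over the list alone, 0 members passed, and 2 had an unadjusted p under 0.05. The list shared 1 tested gene with the natural killer list and was measured in the same arrays in which the T cell list was higher. Infected replicate 2 had the highest array mean at 0.62, and without it the list median was 0.077 and the camera adjusted p was 0.129. Without control replicate 1 the median was 0.22 and the call held.

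Interferon gamma-induced genes had a median of 0.17, with 11 of 17 members above the median of the tested genes (camera adjusted p = 3.7e-05; adjusted p = 0.951 with an estimated correlation). The members with the smallest p were GBP1 at 2.13, CXCL9, a chemokine for activated T cells, at 2.17, GBP2, another guanylate-binding GTPase, at 1.87, and TAP1, the peptide transporter of antigen presentation, at 0.88. The 2 tested probe sets of TAP1 differed in direction. Of the members, 0 passed adjusted over the list alone, and 4 had an unadjusted p under 0.05, all higher. In GBP1, CXCL9 and GBP2 the groups overlapped. Infected replicate 3 had log2 signals of 8.65, 4.84 and 6.60, below control replicate 3 at 9.02, 5.01 and 6.87. CXCL9 passed limma's adjusted threshold in 1 of the leave-one-out fits, the one without infected replicate 3 (fitted log2 fold change 2.86, adjusted p = 0.0356). Its mean log2 signal in controls, 4.63, was under the filter's limit of 5.58. The list means were 0.46 and 0.34 in infected replicates 1 and 2 and -0.089 in infected replicate 3, all above the control range of -0.34 to -0.15 (exact permutation p = 0.1, the smallest possible). T cell markers had means above 0 in the same 3 infected arrays, and natural killer markers in infected replicates 1 and 2 only. The list median was 0.082 without infected replicate 1, 0.11 without control replicate 2 and 0.33 with array weights, and each of these fits kept the call.

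Type I interferon-stimulated genes had a median of 0.24, with 14 of 20 members above the median of the tested genes (camera adjusted p = 0.0038; adjusted p = 0.965 with an estimated correlation). ISG20, an exonuclease of viral RNA, had 1.12 and IFIT2, an inhibitor of viral translation, had 0.95. MX2, an antiviral GTPase, had -0.38 and DDX58, the RNA sensor RIG-I, had -0.30, and the probe sets of IFIT2 differed in direction. Adjusted over the list alone, 0 members passed, and 0 had an unadjusted p under 0.05 by limma. The list shift rested on control replicate 2, whose list mean was -0.82 while the other 5 arrays were between -0.032 and 0.37, and without it the list median was -0.12 (camera adjusted p = 0.291, direction lower). Without control replicate 1, the highest array, it was 0.57. After quantile normalization the adjusted p was 0.143.

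Genes of MHC class I presentation had a median of 0.11 with 11 of 14 members above the median of the tested genes (camera adjusted p = 0.0358; adjusted p = 0.951 with an estimated correlation). TAP1 had 0.88, the presenting molecules SLA-3 and SLA-7 had 0.51 and -0.33, and TAPBP, the chaperone tapasin, had 0.57. Adjusted over the list alone, 0 members passed. The list shared 4 tested genes with the interferon gamma list. The call held in 5 of 15 alternatives, and it was lost after quantile normalization (adjusted p = 0.0618) and without control replicate 3 (adjusted p = 0.1304), the array with the lowest list mean, -0.24. The median was 0.045 without that array, 0.20 without control replicate 1 and 0.16 without infected replicate 3.

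Cell cycle genes had a median of -0.34, with 24 of 25 members below the median of the tested genes (camera adjusted p = 5.5e-07; adjusted p = 0.951 with an estimated correlation). TYMS and RRM2, enzymes of nucleotide synthesis, had relative values of -1.16 and -0.72, and CCNB1, the mitotic cyclin B1, and CDKN3, a phosphatase of the cell cycle, had -0.65 and -0.41. The value of TYMS rested on control replicate 3 and was -0.41 without it, and that of RRM2 was -0.47 without infected replicate 1. Adjusted over the list alone, 0 members passed, and 0 had an unadjusted p under 0.05 by limma. The list means were high in control replicates 2 and 3, at 0.33 and 0.39, and were -0.14 in control replicate 1, inside the infected range of -0.37 to -0.077 (exact permutation p = 0.2). Control replicates 2 and 3 are also the arrays that separated on the principal components. The call held in all 15 alternatives that kept the preset correlation, including the one without control replicate 3 (adjusted p = 3.4e-07).

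**Figure D2:**
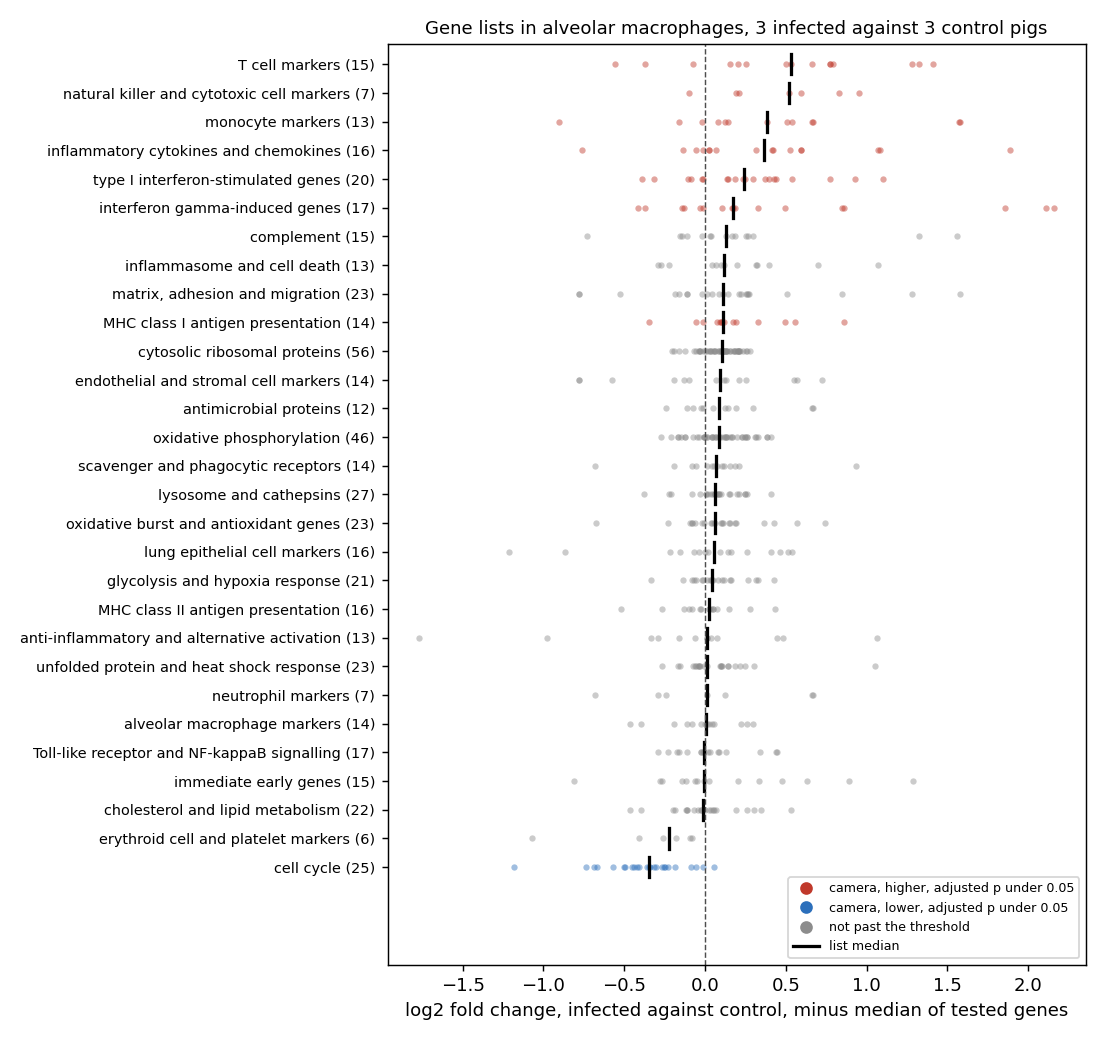
Log2 fold change, infected against control, minus the median of the tested named genes (x axis) for each member of the 29 tested lists (1 row per list, number of tested genes in brackets), with a black bar at each list median and colours for lists past camera's adjusted threshold with its preset correlation. T cell markers have the highest median, 0.53, and cell cycle genes the lowest, -0.34, and none of the coloured lists passed with an estimated correlation.

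**Figure D3:**
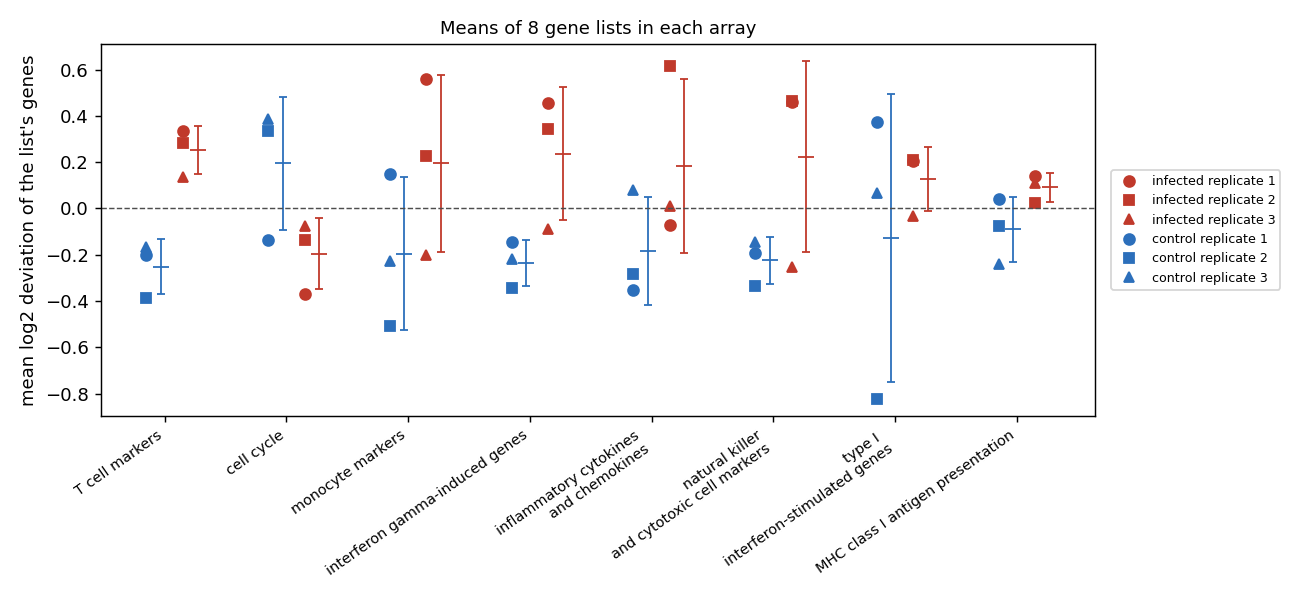
Mean log2 deviation from the average of all 6 arrays, relative to all tested genes (y axis), of the 8 lists that passed camera with its preset correlation, with 1 point per pig and the mean ± SD of each group of 3 beside the points. The groups are fully apart in the T cell and interferon gamma lists and overlap in the other 6.

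Markers of other cells that a lavage can hold showed no list past the threshold besides those of T cells, natural killer cells and monocytes. Erythroid cell and platelet markers had a median of -0.22, with all 6 members below the median of the tested genes (camera adjusted p = 0.0519; adjusted p = 0.951 with an estimated correlation), and the list passed in 5 of 15 alternatives. AHSP, a chaperone of hemoglobin, had -1.05, PPBP, a platelet chemokine, -0.39, GP9, a platelet glycoprotein, -0.17, and ALAS2, the erythroid enzyme of heme synthesis, -0.079. PPBP had -0.23 without control replicate 1 and -0.60 without control replicate 2. ALAS2 had 0.11 without control replicate 1 and -0.31 without control replicate 3. The 16 lung epithelial markers had a median of 0.057 and a mean of -0.0065 (camera adjusted p = 0.869). EPCAM, an epithelial adhesion molecule, had -0.85, TPPP3, a protein of ciliated cells, had -1.20, and the fitted log2 fold changes of ELF3 and KRT18 were -0.34 and -0.40. That of KRT18 rested on control replicate 3 and was -0.018 without it. The 14 endothelial and stromal markers had a median of 0.093 (camera adjusted p = 0.641), with COL5A1, a fibrillar collagen, at 0.74, FLT1, a receptor for VEGF, at -0.56, and VIM, vimentin, at -0.11. Of the 4 tested probe sets of COL5A1, 3 were higher and 1 was lower, with fitted log2 fold changes from -0.12 to 0.54. The 7 neutrophil markers had a median of 0.012 (camera adjusted p = 0.888), with ARG1, arginase, at -0.28, TREM1, an activating receptor of myeloid cells, at -0.66 and PR39, a cathelicidin, at -0.23. Camera's direction for the epithelial, endothelial and neutrophil lists turned under other scalings, while the epithelial median stayed above 0. With array weights the fitted value of TREM1 turned from -0.86 to 0.074.

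In 3 lists of other cells too few members were tested for camera. Among 4 B cell and plasma cell markers, TNFRSF17, the receptor BCMA of plasma cells, had a relative value of 0.95 and an unadjusted p of 0.0285 by limma. JCHAIN, the joining chain of secreted immunoglobulins, had 0.69, and XBP1 and CD40 had 0.028 and 0.038, with fitted values below 0 that turned above 0 after quantile normalization. Of the 3 tested probe sets of CD40, 1 was higher and 2 were lower, with fitted log2 fold changes from -0.16 to 0.61. Among 3 dendritic cell markers the values were 0.51 for FSCN1, -0.057 for CCR7 and 0.028 for XCR1, and the fitted value of XCR1 turned above 0 after quantile normalization. Among 4 eosinophil and mast cell markers they were 0.45 for CCR3, -0.045 for MCT7, 0.012 for KIT and 0.0041 for GATA2, and the fitted values of KIT and GATA2 turned above 0 after quantile normalization. With array weights the fitted values of CCR7 and CCR3 turned, to 0.25 and -0.15. By limma, 0 members of these 3 lists passed adjusted over the list alone.

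Lists of macrophage functions did not pass camera with the preset correlation as reported here, and 4 of them passed, as higher, in some alternatives. The median was 0.0066 for 14 alveolar macrophage markers (adjusted p = 0.641), 0.066 for 14 scavenger and phagocytic receptors (adjusted p = 0.773), 0.064 for 27 genes of lysosomes and cathepsins (adjusted p = 0.641) and 0.061 for 23 genes of the oxidative burst and antioxidant defence (adjusted p = 0.355). For 16 genes of MHC class II presentation it was 0.024 (adjusted p = 0.758), and for 17 genes of Toll-like receptor and NF-kappaB signalling it was -0.0075 (adjusted p = 0.872). The 13 genes of the inflammasome and cell death had 0.12 (adjusted p = 0.075) and the 15 complement genes had 0.13 (adjusted p = 0.0843), and the array means of both lists were fully apart between the groups (exact permutation p = 0.1, the smallest possible). Such a separation was found in 4 of 29 lists, including 2 of the 8 that passed camera, where chance gives 2.9 lists on average. Genes of matrix, adhesion and migration had 0.11 (adjusted p = 0.08), antimicrobial proteins 0.087 (adjusted p = 0.348) and genes of the anti-inflammatory and alternative activation state 0.015 (adjusted p = 0.641). With the stricter filter the inflammasome, matrix and antimicrobial lists passed (adjusted p = 0.011, 0.0229 and 0.0295). Without infected replicate 3 the complement and antimicrobial lists passed (adjusted p = 0.0314 and 0.0433), as did the matrix list without infected replicate 2 (adjusted p = 0.0355) and without control replicate 1 (adjusted p = 0.0393). With an estimated correlation on all 6 arrays the adjusted p was 0.965 for each of these 4 lists.

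Lists of housekeeping functions and stress responses did not pass as reported here either. The medians were 0.11 for 56 cytosolic ribosomal proteins and 0.085 for 46 genes of oxidative phosphorylation (camera adjusted p = 0.298 for both), 0.042 for glycolysis and the hypoxia response (adjusted p = 0.646), -0.012 for cholesterol and lipid metabolism (adjusted p = 0.963), 0.013 for the unfolded protein and heat shock response (adjusted p = 0.56) and -0.0085 for immediate early genes (adjusted p = 0.298). The ribosomal list passed without control replicate 3 (adjusted p = 0.0362), after centring (adjusted p = 0.0054) and with array weights (adjusted p = 0.0279), and the oxidative phosphorylation list after centring (adjusted p = 0.0499). Without control replicate 2 the immediate early and unfolded protein lists passed as higher (adjusted p = 0.0034 and 0.0098), and without infected replicate 3 the immediate early list did (adjusted p = 0.0401). With an estimated correlation on all 6 arrays the adjusted p was 0.965 for each of these 4 lists. The median and the mean of a list differed in sign in the alternative activation, MHC class II, Toll-like receptor, alveolar macrophage, epithelial, endothelial and immediate early lists, and camera's direction followed the mean except in the epithelial and endothelial lists.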

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

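Quantile normalization without control replicate 3 and the exact tests of list means were chosen after the results were seen, and the other settings were planned. By limma, 0 genes passed at an adjusted p under 0.05 in each setting except array weights, the replicate block and 2 of the fits that left out a pig, and the count at an unadjusted p under 0.05 was 299 as reported and 138 to 1697 in the other settings. Array weights gave 4 genes (C1H15orf48, S100A4, CXCR6 and LOC102160313). Leaving out 1 pig gave 0 to 5, with 1 gene (CXCL9) without infected replicate 3 and 5 without control replicate 1 (LRRFIP1, FN1, 2 unnamed probe sets and LOC396781, named here after its value was seen). The 135 probe sets at an unadjusted p under 0.05 and 2-fold became 244 with no filter, 81 with the stricter filter, 80 with the offset or with the 3' to 5' covariate and 206 with array weights. Leaving out 1 pig gave 101 to 889, with 889 without control replicate 1 and 232 without infected replicate 2. The filters change how many probe sets are tested, and the cause was not tested for the other settings.

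The labels do not say that the replicate numbers pair the pigs. The deviations of same-numbered arrays correlated at 0.22, -0.14 and -0.025, and of the 3 infected arrays 1 correlated best with its own number. These few correlations cannot tell whether the pigs were paired. With the number as a block, 82 genes passed (38 higher, 44 lower) and 293 reached an unadjusted p under 0.05 and 2-fold. That fit had 2 residual degrees of freedom and its prior variance was taken as fixed. The block gave 8 lists, with MHC class I lost (adjusted p = 0.101) and the erythroid list gained (0.0335).

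The 8 lists became 0 with an estimated correlation and 0 by fry, and 6 to 12 in the other settings. T cell, monocyte, natural killer, interferon gamma and cell cycle lists passed in all 15 settings with the preset correlation. Over these 15 the median ranged from 0.20 to 0.68 for T cell, 0.082 to 0.33 for interferon gamma and -0.31 to -0.099 for erythroid genes. Besides the lists named beside their values, complement (adjusted p = 0.013) and ribosomal genes (0.0127) passed with the mean of all probe sets of a gene, and inflammasome (0.029) and ribosomal genes (0.030) after quantile normalization without control replicate 3. The medians over the fits that left out a pig ranged from 0.077 to 0.45 for cytokines, -0.12 to 0.57 for type I interferon, 0.045 to 0.20 for MHC class I, -0.31 to -0.17 for erythroid, -0.041 to 0.11 for neutrophil, 0.00029 to 0.11 for epithelial and -0.072 to 0.26 for endothelial genes. The direction of camera, or for fry that of fry's own test against no change, turned for 3 lists that never passed and, without control replicate 2, for type I interferon, which had passed. Neutrophil medians then were -0.045 with no filter, -0.0063 after quantile normalization, 0.012 after centring and by fry, and -0.0061 after quantile normalization without control replicate 3. Endothelial medians were 0.081 after quantile normalization, -0.024 with array weights, -0.064 after quantile normalization without control replicate 3 and 0.093 by fry, and the epithelial median was 0.057 after centring and by fry. The erythroid list passed in 5 of 15 settings, with adjusted p from 0.0202 without control replicate 2 to 0.323.

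Of 82 named probe sets 68 kept their fitted direction in every setting in which it was checked, and the stricter filter left out 31 of the 82. Directions were not checked in the fit with the 3' to 5' covariate. Fitted log2 fold changes near 0 turned after quantile normalization or centring for XCR1 (0.045 and 0.036), KIT (0.0070 and 0.021), GATA2 (0.029 and 0.013), XBP1 (0.043 and 0.037) and CD40 (0.053 and 0.047), and for CD3D (0.20 and 0.18), which like CD3E, CD247, LAT and CD8B was given these fits after its value was seen. With array weights the direction turned for TREM1 (from -0.86 to 0.074), CCR7 (0.25), GATA2 (0.028), CCR3 (-0.15), CD8B (0.077) and CD3D (0.30), and after quantile normalization without control replicate 3 for CCR7 (0.10), CCR3 (-0.12), XBP1 (0.019), LAT (0.016), CD8B (0.28) and CD3D (0.33). Leaving out 1 pig gave -0.60 to 0.10 for CCR7, -0.087 to 0.53 for CCR3, -0.33 to 0.035 for XBP1, -1.23 to 0.045 for LAT, -1.04 to 0.26 for CD8B, -0.30 to 0.33 for CD3D, -0.043 to 0.31 for CD247, -0.47 to 1.65 for JCHAIN and -0.77 to 0.0071 for DDX58. Relative to the median of the same fit, leaving out 1 pig moved 39 of the 82 by over 1.5 times, 26 of them without control replicate 3, and 12 had the other sign in some fit. Without control replicate 3 the relative values were 0.25 for CCL5, 0.17 for TAPBP, 0.27 for COL5A1, -0.27 for FLT1, -0.35 for TREM1, -0.11 for CCR3 and -0.16 for SLA-7. Without control replicate 2 they were 0.60 for IL18, 0.74 for ISG20 and -0.16 for JCHAIN, and without control replicate 1 1.49 for IFIT2, -1.14 for CXCL2 and -0.70 for AHSP. Without infected replicate 2 TPPP3 had -0.71, and without infected replicate 3 AHSP had -0.45. The group difference in the 3' to 5' ratio, 0.23, was 0.57 by ACTB alone, -0.12 by GAPDH alone and -0.13 to 0.55 when a pig was left out, and that of the array median was -0.32 to 0.0092. What the depth of an array limits, signal over background, could not be set without detection calls.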

Other observations

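The tests on control replicate 3 by scaling and RNA integrity, the tests on the T cell list, and the counts of genes over other splits were chosen after the results were seen; the test by pairs of probe sets and the count of lists over other splits were not.

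Several gene groups differed as much between pigs of 1 group as between the groups. Type I interferon-stimulated genes had a list mean of -0.82 in control replicate 2 and 0.37 in control replicate 1, so the controls spanned the range of all pigs. Infected replicate 3 differed from the other infected pigs in several lists at once. Its list means were -0.25 for natural killer, -0.20 for monocyte and -0.089 for interferon gamma-induced genes, where infected replicate 1 had 0.46, 0.56 and 0.46. Inflammatory cytokines and chemokines had a list mean of 0.62 and immediate early genes one of 0.41 in infected replicate 2, against -0.071 and -0.038 in infected replicate 1. These values carry no test, and the animals' own clinical course is not given in the sources used here.

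T cell markers were higher in infected pigs by a median of 0.53 relative to the tested genes. A lower share of macrophages in the lavage, with every other cell type raised alike, was examined by pooled markers of other cells. The T cell list lay 0.54 above the pooled markers of granulocytes, epithelium, stroma and blood (95% bootstrap interval over genes 0.22 to 0.85, with 15 and 47 genes). It lay 0.40 above a pool of 70 genes (0.086 to 0.71). That pool also held the natural killer, monocyte, B cell and dendritic markers left out of the first. Both intervals cover the spread of genes in the same 6 arrays, not that of pigs. The T cell list was also picked for its smallest camera p, so the comparison cannot decide on this cause. The deviating control replicate 3 is argued against as the whole cause of the direction. The list means of control replicates 1 and 2, -0.20 and -0.38, also lay below that of each infected pig. Without control replicate 3 the list median was 0.28, and camera gave an adjusted p of 8.8e-09. That p rests on the preset correlation, and 3 against 2 pigs cannot give an exact p under 0.1. More T cells in the lavage cannot be told from a change of transcription within the same T cells, because the 6 of 6 genes of the receptor complex and its signalling above the median (CD3D, CD3E, CD3G, CD247, CD2 and LCK) are all members of the list, CD3D and CD247 had fitted values of -0.028 and 0.075, and LAT and CD8B lay below at -0.54 and -0.35. The list call is lost with an estimated correlation (adjusted p = 0.836), and no count of cells is given in the sources used here.

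Control replicate 3 stood apart from the other arrays. Its scale did differ, with a trimmed mean signal of 384 against 234 to 254 in the other arrays. A different scaling factor is argued against only as the whole cause, since a factor leaves ranks as they are. The highest Spearman correlation of control replicate 3 with another array was 0.941, below the lowest among the other 5, 0.971. RNA more degraded than in the other pigs is argued against. Its 3' to 5' ratio was 1.60 on the log2 scale, lower than in each other array (2.22 to 3.001). Whether this lower ratio of control replicate 3, a sign of more intact RNA, itself set the array apart was not tested. A candidate explanation, at least in part, is a difference of single probe sets. Across 1433 genes its deviations correlated between 2 probe sets of a gene at only 0.23 (95% bootstrap interval 0.17 to 0.29), against 0.39 to 0.53 in the other arrays. These deviations also had the largest SD, 0.65 against 0.27 to 0.45. The low correlation therefore does not exclude a large difference of transcript levels, which both probe sets would share. No biological explanation was tested, and a difference of that pig or of its hybridization batch stays open.

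The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. By limma 0 genes changed in the real split (299 at an unadjusted p under 0.05) and at most 3 in another, so that 10 of the 10 splits gave as many. At an unadjusted p under 0.05 and 2-fold the real count was 135 and the highest other 423, and 4 splits gave as many. The split with 423 set infected replicates 1 and 3 and control replicate 1 against the rest. These arrays had the lowest values on the first principal component, -28.6, -21.9 and -25.8. Infected replicate 2 and control replicates 2 and 3 had -7.2, -12.0 and 95.4, so the split follows the main axis of variation of the arrays. It was picked as the largest of the others, and no test says how large that count gets by chance. Gene lists shifted numbered 8 in the real split and at most 12 in another, and 3 splits gave as many.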
